A study of Homo sapiens with 12 samples.

How the data were processed

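RNA-seq of the TMD8 lymphoma line was analysed in 12 libraries: DMSO, C, S and SC, 3 each, after 24 h. Treatment was with 375 nM chidamide, 1 µM selinexor or both. The labels describe oligo(dT) selection of mRNA. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the hg38 genome, without saying how each was used. The deposited values are TPM per the file headers, made by the authors; the samples' own description calls the same libraries FPKM. The plan made beforehand assumed FPKM, and the same steps were applied to the TPM values. Sums between 818771 and 850633 per library fall short of the full TPM total; the table holds 8060 gene symbols rather than all genes, and how these were chosen is not stated.

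Only these processed values were used; reads were not analysed here. TPM keeps no read count, so depth is unknown and no counting intervals are given. Precision comes from the spread between the 3 libraries of a group. Gene positions came from GENCODE release 29 on GRCh38, counted from 1, where 7885 of the 8060 symbols were found. For 12 genes the values were identical to those of another gene, and they were left in.

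Values were transformed to log2(TPM + 1). Genes with at least 1 TPM in at least 3 of the 12 libraries were kept, 7435 in all. All libraries entered 1 linear model with a coefficient per group in limma 3.58.1 (R 4.3.3), with trend and robust empirical Bayes moderation. Tests were two-sided with Benjamini-Hochberg adjustment within each comparison at 0.05. The comparisons were C, S and SC against DMSO, SC against each single agent, S against C, and the interaction (SC minus C) minus (S minus DMSO). Gene sets were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data, where limma also uses the 8 residual degrees of freedom in place of the number of genes. The 42 gene lists were fixed before the data were examined, with 772 of 1088 members in the table; 34 lists had the 5 tested members that the test required. The overlap of single-agent changes was set beside 50 simulations of unchanged groups sharing the DMSO libraries. For the closing section, the interaction of mitosis genes was compared with that of the 100 other genes nearest in SC vs DMSO change. This was a score per library with a 95% interval over the libraries.

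Genes were named by a rule made before the data were examined. It took 14 targets always (11 were in the table), and the 6 largest rises and 6 largest falls per comparison among genes past the threshold, with a mean of at least 1 TPM in a group compared and no overlap between the libraries compared (overlap was allowed for the interaction). Immunoglobulin and T-cell receptor segments, XIST, genes annotated on chromosome Y and unnamed loci were left out. From each list past the set test it took up to 3 members with the smallest adjusted p in the set's direction. Genes named outside the rule are members of fixed lists or markers and were chosen after their values were seen: CHAC1 and SLC43A2 in the report, and in the closing section the markers of other cell types and those so described there.

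The alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, rescaling to equal sums, quantile normalization, trimmed-mean scaling, limma without trend or robust moderation, the replicate number as a block, only the groups compared, a minimum log2 change of 1, and leaving out each library. A scaling of SC that puts the empty stretch of its ratio to DMSO at 0 was added after seeing the data. Replicate numbers are not stated to pair the libraries and were not modelled in the results reported. The model was tested on simulated data of 7435 genes, most of them unchanged, with noise independent between genes. At a true log2 change of 0.5 it recovered 94.0% of changed genes for C against DMSO and 79.1% for the interaction. There were 17 and 10 false calls among the unchanged genes. In the data most genes were called in the pairwise comparisons, so these rates need not carry over.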

Results

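RNA was sequenced from TMD8, an established human B-cell lymphoma line, in 4 groups of 3 libraries. The groups were vehicle (DMSO), the single agents coded C and S, and both agents together (SC), each for 24 h. Chidamide (375 nM), an inhibitor of histone deacetylases (HDACs), and selinexor (1 µM), which blocks the nuclear exporter XPO1, were the agents. The labels give C as selinexor and S as chidamide, which is the reverse of the initials, so the groups keep their codes here. The study's title ties the pair of agents to survivin and to the PI3K/AKT pathway.

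The table gave a TPM value per gene symbol and library, and 7435 genes passed the expression filter. TPM keeps no read count, so the depth of each library is unknown. The values summed to between 818771 and 850633 TPM per library. Correlation of log2 values was at least 0.996 within groups and at most 0.982 between groups, and 0 libraries were closest to a library of another group. Values are mean TPM ± SD over 3 libraries, and changes are log2 ± SE on the log2(TPM + 1) scale, which understates changes of low genes. Nothing states that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

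The table was not a full transcriptome. Its order followed the SC to DMSO ratio of each gene (rank correlation 0.999 across genes, which are not independent replicates). Of 5104 genes at 10 TPM or more in DMSO, 6 had a log2 ratio of SC to DMSO within 0.05 of 0.24, against 362 for C to DMSO and 439 for S to DMSO. Counts and shares below therefore describe the genes of this table. Survivin (BIRC5), HDAC2 and PIK3CA had no entry in it and were not analysed here, nor were mitochondrially encoded genes.

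**Figure D1:**
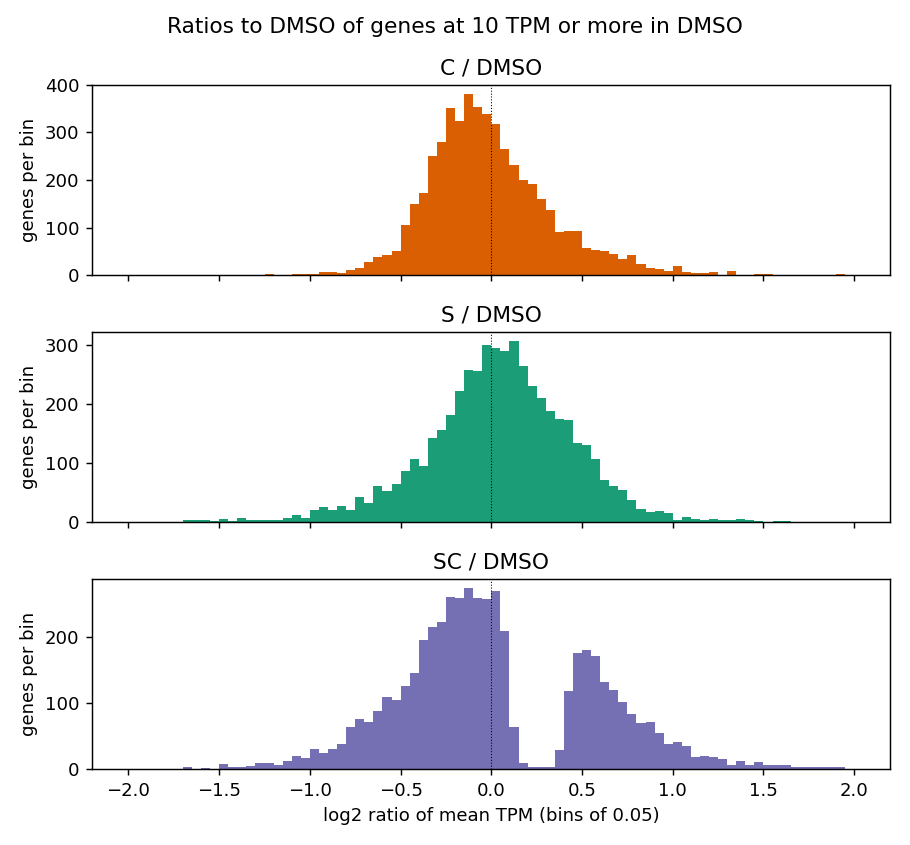
Number of genes per bin of 0.05 (vertical axis) by the log2 ratio of mean TPM to DMSO (horizontal axis) for C, S and SC, over the 5104 genes at 10 TPM or more in DMSO; the dotted line marks 0. Only the SC panel has an empty stretch, with 6 genes within 0.05 of 0.24.

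The fixed targets lie at these positions on GRCh38 (GENCODE release 29, counted from 1): XPO1 on chromosome 2, 61477849 to 61538626; HDAC1 on chromosome 1, 32292086 to 32333635; PIK3CD on chromosome 1, 9651732 to 9729114. AKT1 lies on chromosome 14, 104769349 to 104795751, TP53 on chromosome 17, 7661779 to 7687550 and CDKN1A on chromosome 6, 36676460 to 36687339. In DMSO, XPO1 stood at 272 ± 21.7 TPM, HDAC1 at 193 ± 4.60, PIK3CD at 81.4 ± 3.07, AKT1 at 105 ± 5.14, TP53 at 254 ± 0.814 and CDKN1A at 0.503 ± 0.101 TPM.

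**Figure D2:**
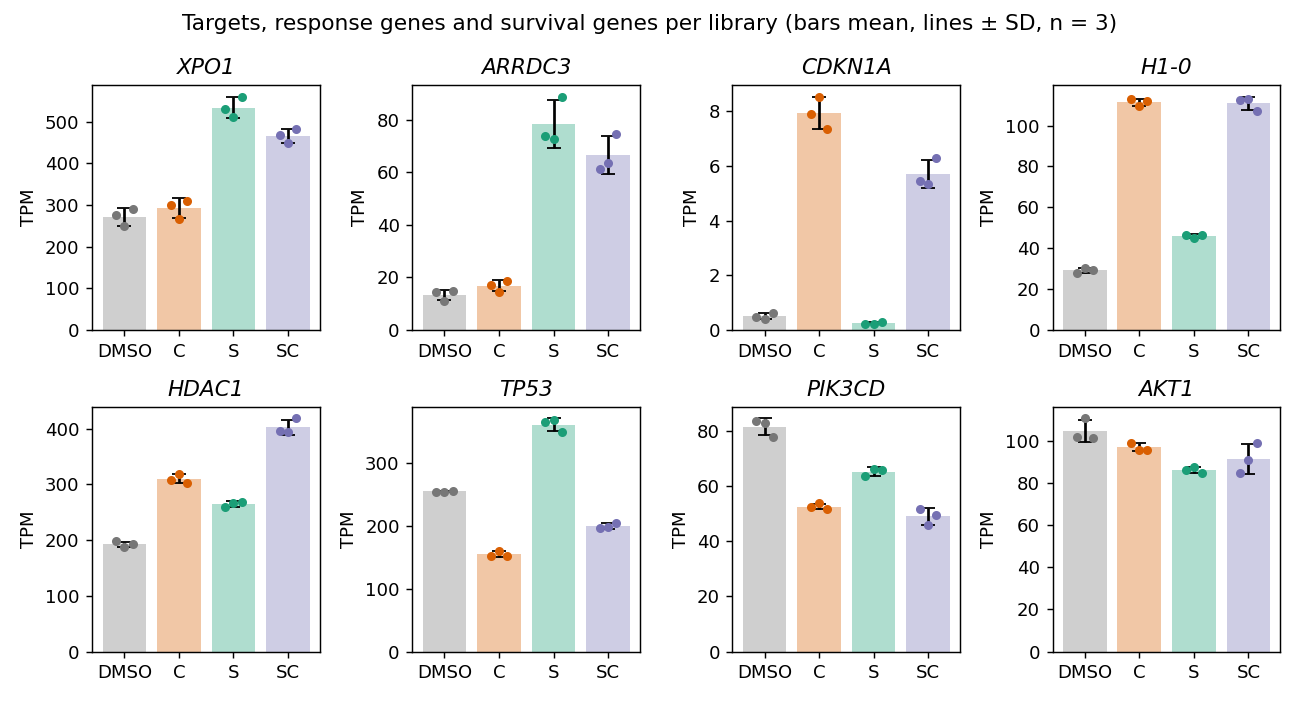
TPM of 8 genes (vertical axes, each from 0) in the DMSO, C, S and SC libraries; points are libraries, bars are means and lines are ± SD (n = 3). XPO1 reached 533 TPM in S against 272 in DMSO, and CDKN1A reached 7.93 TPM in C against 0.503.

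The comparison of C with DMSO asks what the agent coded C changed on its own. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose to 7.93 ± 0.585 TPM from 0.503 ± 0.101 (log2 change 2.57 ± 0.083, adjusted p = 6.35e-11), and the linker histone H1-0 rose to 111 ± 1.78 from 29.1 ± 1.37 TPM. As sets, MHC class II genes were higher, and nucleolar and biosynthetic MYC targets and genes of mitochondrial respiration lower. In all, 5029 of 7435 genes changed (limma), 2915 higher and 2114 lower, against 2135 higher and 2696 lower after quantile normalization.

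Among the fixed targets in C, HDAC1 rose by 0.68 ± 0.033 (adjusted p = 2.02e-09), while TP53 (-0.71 ± 0.031), HDAC10 (-0.41 ± 0.11) and PIK3CD (-0.62 ± 0.047, adjusted p = 1.15e-07), a catalytic PI3K subunit, fell. MYC rose by 0.17 ± 0.034 (adjusted p = 5.35e-04). XPO1 did not pass the test (0.10 ± 0.065, adjusted p = 0.174) but did after quantile normalization, at 0.20, and without C replicate 2, at 0.17. AKT1 did not pass either (-0.11 ± 0.051, adjusted p = 0.0735) but did without SC replicate 1 or SC replicate 3, which share the error estimate, at -0.11 and -0.11, and with trimmed-mean scaling, at -0.16. HDAC3 (-0.044 ± 0.044), BCL2 (-0.034 ± 0.042) and MCL1 (0.029 ± 0.036) did not pass, though BCL2 did with trimmed-mean scaling (-0.088) and MCL1 after quantile normalization (0.14). The steepest rises, with no overlap between libraries, were those of CNN2, a calponin, from 2.70 ± 0.479 to 66.7 ± 1.90 TPM, then GAMT (2.99 ± 0.11), ZNF385A (2.97 ± 0.093), GMPR (2.91 ± 0.15), MOXD1 (2.74 ± 0.068) and TMEM119 (2.74 ± 0.10). The steepest falls were in IGLL1, a surrogate light chain of B-cell precursors, from 133 ± 6.68 to 13.5 ± 1.09 TPM, then LTB, encoding lymphotoxin beta (-1.84 ± 0.095), SCX (-1.50 ± 0.19), ALDH3B2 (-1.49 ± 0.10), RSC1A1 (-1.35 ± 0.35) and TUBB3 (-1.25 ± 0.047). RSC1A1 lies within another gene, DDI2, so its value is uncertain.

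Of 38 nucleolar and biosynthetic MYC targets, 2 rose, 34 fell and 2 did not pass, with WDR74 at -0.47 ± 0.030 and CDK4 at -0.41 ± 0.031 (adjusted p = 3.60e-08). In the DNA replication and E2F list 2 rose, 33 fell and 7 did not pass, with MCM7 of the replicative helicase at -0.59 ± 0.032 (adjusted p = 3.60e-08, and adjusted p = 0.0729 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation went down: 0 rose, 27 fell and 3 did not pass, with CYC1 at -0.71 ± 0.040 (adjusted p = 3.60e-08). For mitosis 2 rose, 22 fell and 12 did not pass, with cyclin CCNA2 at -0.71 ± 0.038 and PLK1 at -0.40 ± 0.037 (adjusted p = 7.07e-05, and adjusted p = 0.182 with an estimated correlation). For homologous recombination and Fanconi repair 1 rose, 8 fell and 11 did not pass, with CHEK1 at -0.41 ± 0.057 (adjusted p = 0.00852, and adjusted p = 0.460 with an estimated correlation). For nuclear transport 0 rose, 20 fell and 9 did not pass, with IPO4 at -0.68 ± 0.049 (adjusted p = 5.54e-05, and adjusted p = 0.211 with an estimated correlation). Proteasome genes (3 rose, 19 fell and 8 did not pass, adjusted p = 8.15e-04), heat shock genes (3 rose, 12 fell and 3 did not pass, adjusted p = 0.0252, and adjusted p = 0.211 with an estimated correlation) and glycolysis genes (4 rose, 13 fell and 5 did not pass, adjusted p = 0.0228, and adjusted p = 0.641 with an estimated correlation) were lower as sets, calls that quantile normalization ended; a filter of 5 TPM also ended the heat shock call.

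Of 17 MHC class II genes, 15 rose, 1 fell and 1 did not pass, with HLA-DRA reaching 1918 ± 76.2 TPM from 1033 ± 16.7 and HLA-DQB1 changing by 1.51 ± 0.048 (adjusted p = 5.54e-05). Of 29 interferon-stimulated genes, 23 rose, 2 fell and 4 did not pass, with OAS3 at 1.77 ± 0.056 and IFI44L at 2.11 ± 0.089 (adjusted p = 7.58e-04, and adjusted p = 0.131 with an estimated correlation). Among known HDAC-inhibitor response genes 13 rose, 2 fell and 3 did not pass, with SYT11 at 2.55 ± 0.070 (adjusted p = 0.00369). Among p53 targets 14 rose, 0 fell and 8 did not pass, with DDB2 at 2.09 ± 0.12 and the death receptor TNFRSF10B at 0.67 ± 0.046 (adjusted p = 0.00178, and adjusted p = 0.0827 with an estimated correlation). FoxO targets (14 rose, 0 fell and 4 did not pass, adjusted p = 7.52e-04, and adjusted p = 0.153 with an estimated correlation) included BCL6 at 0.79 ± 0.044. AP-1 and immediate early genes (12 rose, 0 fell and 2 did not pass, adjusted p = 0.00210) included IER3 at 1.37 ± 0.12, and plasma-cell genes (9 rose, 2 fell and 2 did not pass, adjusted p = 0.0252, and adjusted p = 0.108 with an estimated correlation) included SDC1 at 2.02 ± 0.090. Adjusted over the list alone, the counts were the same except for FoxO targets (15 rose) and glycolysis (14 fell). With an estimated correlation the MYC, oxidative phosphorylation, proteasome, MHC class II, HDAC-inhibitor and AP-1 calls held.

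The comparison of S with DMSO asks the same of the agent coded S. XPO1 rose to 533 ± 25.2 TPM from 272 ± 21.7 (log2 change 0.97 ± 0.065, adjusted p = 4.55e-08), and ARRDC3, an arrestin-domain gene among blood markers of XPO1 inhibitors, rose to 78.5 ± 9.03 from 13.4 ± 2.04 TPM. Genes of the unfolded protein response of the endoplasmic reticulum (ER) were lower as a set. TXNIP, a thioredoxin-binding FoxO target, rose to 182 ± 3.66 from 46.2 ± 2.44 TPM. In all, 4955 genes changed (limma), 3135 higher and 1820 lower, against 2397 higher and 2259 lower after quantile normalization and 2535 higher and 2325 lower with trimmed-mean scaling.

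Among the targets in S, HDAC1 (0.46 ± 0.033, adjusted p = 7.84e-08), TP53 (0.50 ± 0.031) and BCL2 (0.40 ± 0.042, adjusted p = 2.63e-06), which blocks apoptosis, rose. AKT1 fell by 0.28 on the log2 scale (adjusted p = 3.38e-04) and PIK3CD by 0.32 (adjusted p = 5.71e-05). CDKN1A fell (-0.27 ± 0.083, adjusted p = 0.0106), at under 1 TPM in both groups. MCL1 fell as well (-0.12 ± 0.036, adjusted p = 0.00939), a call that ended when each library was rescaled to the same sum (-0.083). MYC (0.024 ± 0.034), HDAC3 (0.045 ± 0.044) and HDAC10 (-0.040 ± 0.11) did not pass. The steepest rises were those of MDK, the growth factor midkine, from 12.7 ± 2.21 to 141 ± 0.865 TPM, ARRDC3, CRIP1 (2.02 ± 0.094), TXNIP and the histone copies H2AC18 and H2AC19 (2.12 ± 0.072), whose values were identical and cannot be assigned to either. The steepest falls included PIR (-1.97 ± 0.051), PFKFB4, a regulator of glycolysis (-1.83 ± 0.12), ALDH1L2 (-1.79 ± 0.064), MEF2B (-1.75 ± 0.17) and PTPN3 (-1.73 ± 0.093). SMIM11A was listed at 0 in all S libraries and at 3.21 ± 0.0529 TPM in DMSO, and it has a near-identical copy, so its value is uncertain.

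For the integrated stress response 2 rose, 21 fell and 0 did not pass, with the amino-acid transporter SLC7A5 at -1.40 ± 0.029 and asparagine synthetase ASNS at -1.15 ± 0.029 (adjusted p = 8.42e-11, and adjusted p = 0.194 with an estimated correlation). For the ER unfolded protein response 0 rose, 15 fell and 1 did not pass, with the chaperone HSPA5 going from 474 ± 8.95 to 185 ± 0.401 TPM (adjusted p = 4.15e-10). Of 22 glycolysis genes 1 rose, 20 fell and 1 did not pass, with hexokinase HK2 at -1.36 ± 0.046 and PFKL at -1.07 ± 0.043 (adjusted p = 2.51e-10, and adjusted p = 0.199 with an estimated correlation). For cholesterol synthesis 3 rose, 13 fell and 3 did not pass, with LDLR at -0.71 ± 0.049 and HMGCS1 at -0.65 ± 0.055 (adjusted p = 0.00373, and adjusted p = 0.194 with an estimated correlation). Ribosomal protein genes (3 rose, 27 fell and 14 did not pass, adjusted p = 1.11e-06, and adjusted p = 0.300 with an estimated correlation) included RPL10A at -0.85 ± 0.041, and nucleolar MYC targets (8 rose, 18 fell and 12 did not pass, adjusted p = 0.0277, and adjusted p = 0.246 with an estimated correlation) included BOP1 at -0.84 ± 0.045. Quantile normalization ended both of these calls.

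Proteasome genes (6 rose, 14 fell and 10 did not pass, median -0.044, adjusted p = 0.0455, and adjusted p = 0.194 with an estimated correlation) included PSMD7 at -0.97 ± 0.034. That set call ended under quantile normalization, rescaling to equal sums, a filter of 5 TPM, a fit of the groups compared alone, and without DMSO replicate 2, C replicate 2, S replicate 3, SC replicate 1 or SC replicate 3, where the medians were -0.042, -0.044, -0.030, -0.044 and -0.044. Upward, FoxO targets (15 rose, 2 fell and 1 did not pass, adjusted p = 0.00322, and adjusted p = 0.246 with an estimated correlation) included BCL6 at 1.41 ± 0.044 and CCNG2 at 1.29 ± 0.073. Known HDAC-inhibitor response genes (14 rose, 4 fell and 0 did not pass, adjusted p = 0.0200, and adjusted p = 0.194 with an estimated correlation) included SAT1, of polyamine breakdown, at 1.60 ± 0.045 and H2BC21 at 1.35 ± 0.059. Interferon-stimulated genes (21 rose, 2 fell and 6 did not pass, adjusted p = 0.0304, and adjusted p = 0.300 with an estimated correlation) included TRIM22 at 1.35 ± 0.075. Adjusted over the list alone, the counts were the same except that 3 interferon-stimulated genes fell. The ER call alone held with an estimated correlation, at adjusted p = 0.0230. Of the XPO1-inhibitor blood markers 2 rose, 2 fell and 1 did not pass; those lower were CHAC1 (-1.04 ± 0.12) and SLC43A2 (-0.18 ± 0.053).

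The comparison of SC with DMSO asks what both agents did together. CNN2 rose from 2.70 ± 0.479 to 104 ± 3.17 TPM, MDK from 12.7 ± 2.21 to 192 ± 8.81 and SAT1 from 25.1 ± 0.929 to 138 ± 3.44. Hexokinase HK2 fell from 105 ± 3.47 to 20.4 ± 1.38 TPM and lactate dehydrogenase LDHA from 3486 ± 104 to 1161 ± 102. XPO1 (0.78 ± 0.065), HDAC1 (1.06 ± 0.033) and CDKN1A (2.15 ± 0.083, adjusted p = 6.05e-11) rose. In all, 6126 genes changed (limma), 3576 higher and 2550 lower, but the split depended on scaling: 2804 higher and 3261 lower after quantile normalization, 3466 higher and 3742 lower with trimmed-mean scaling and 3373 higher and 3835 lower with SC scaled so that the empty stretch lay at 0. Genes in that stretch are nearly absent from the table, which can raise the share called for SC. The count therefore cannot be set against those for C and S.

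The median over all genes was 0.059, and moved to -0.048, -0.13 and -0.18 under these scalings; the set tests compare each list with the other genes and so are relative to that shift. PIK3CD (-0.72 ± 0.047, adjusted p = 8.18e-09), TP53 (-0.35 ± 0.031) and AKT1 (-0.20 ± 0.051, adjusted p = 0.00300) fell. HDAC10 (-0.16 ± 0.11) did not pass but was lower after quantile normalization (-0.89), with trimmed-mean scaling (-0.32) and with the empty stretch at 0 (-0.35). Nor did HDAC3 (0.0055 ± 0.044), MYC (0.030 ± 0.034), BCL2 (0.048 ± 0.042) and MCL1 (0.044 ± 0.036) pass, which turned to -0.19, -0.16, -0.15 and -0.15 with trimmed-mean scaling, whereas MYC (0.15), BCL2 (0.12) and MCL1 (0.15) were higher after quantile normalization. Rescaling to equal sums also brought MYC (0.081) and MCL1 (0.095) past the test. Besides CNN2 and MDK, the steepest rises were in AKR1C3, an aldo-keto reductase with close paralogs (4.08 ± 0.11), IFITM1 (3.60 ± 0.20), TNNT1 (3.58 ± 0.14) and SFXN3 (3.58 ± 0.065). Besides HK2, the steepest falls were in IGLL1 (-3.09 ± 0.072), LRRC26 (-2.25 ± 0.15), PCYT2 (-1.98 ± 0.072) and WDR4 (-1.92 ± 0.062), and SMIM11A was listed at 0 in all SC libraries.

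Of 38 nucleolar MYC targets in SC, 1 rose, 34 fell and 3 did not pass, with spermidine synthase SRM at -1.16 ± 0.034 and PES1 at -0.97 ± 0.041 (adjusted p = 2.77e-09). In the replication list 1 rose, 33 fell and 8 did not pass, with UHRF1 at -0.87 ± 0.033 (adjusted p = 1.09e-06, and adjusted p = 0.101 with an estimated correlation). Of 22 glycolysis genes 2 rose, 20 fell and 0 did not pass, with ALDOA at -1.11 ± 0.030 (adjusted p = 1.09e-06, and adjusted p = 0.238 with an estimated correlation). For the integrated stress response 3 rose, 20 fell and 0 did not pass, with ATF5 at -1.46 ± 0.036 (adjusted p = 6.32e-06, and adjusted p = 0.191 with an estimated correlation). For the ER response 0 rose, 14 fell and 2 did not pass, with CRELD2 at -1.32 ± 0.069 (adjusted p = 3.71e-05). Nuclear transport (5 rose, 18 fell and 6 did not pass, adjusted p = 5.40e-04, and adjusted p = 0.305 with an estimated correlation) included IPO4 at -1.46 ± 0.049. The proteasome (0 rose, 24 fell and 6 did not pass, adjusted p = 7.14e-06) and oxidative phosphorylation (2 rose, 23 fell and 5 did not pass, adjusted p = 2.15e-05, and adjusted p = 0.0817 with an estimated correlation) were lower as sets, calls that quantile normalization ended. Ribosomal protein genes (4 rose, 26 fell and 14 did not pass, adjusted p = 2.59e-04, and adjusted p = 0.420 with an estimated correlation) had a median of -0.12, which quantile normalization turned to 0.018 while ending the call.

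Of 29 interferon-stimulated genes in SC, 27 rose, 2 fell and 0 did not pass, with IFI6 at 2.32 ± 0.070 (adjusted p = 5.31e-05, and adjusted p = 0.0991 with an estimated correlation). Of 18 HDAC-inhibitor response genes 15 rose, 3 fell and 0 did not pass (adjusted p = 0.00233). Of 18 FoxO targets 17 rose, 1 fell and 0 did not pass, with BCL6 at 1.80 ± 0.044 (adjusted p = 2.32e-04, and adjusted p = 0.151 with an estimated correlation). Among p53 targets 18 rose, 4 fell and 0 did not pass, with TP53INP1 at 1.90 ± 0.086 (adjusted p = 0.0115, and adjusted p = 0.155 with an estimated correlation). MHC class II genes (13 rose, 1 fell and 3 did not pass, adjusted p = 0.0115, and adjusted p = 0.191 with an estimated correlation) included HLA-DOA at 1.09 ± 0.038, and AP-1 genes (12 rose, 0 fell and 2 did not pass, adjusted p = 0.00203) included IER3 at 2.61 ± 0.12. Adjusted over the list alone, the counts were the same except for nuclear transport (4 rose, 17 fell). The MYC, ER, proteasome, HDAC-inhibitor and AP-1 calls held with an estimated correlation.

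**Figure D3:**
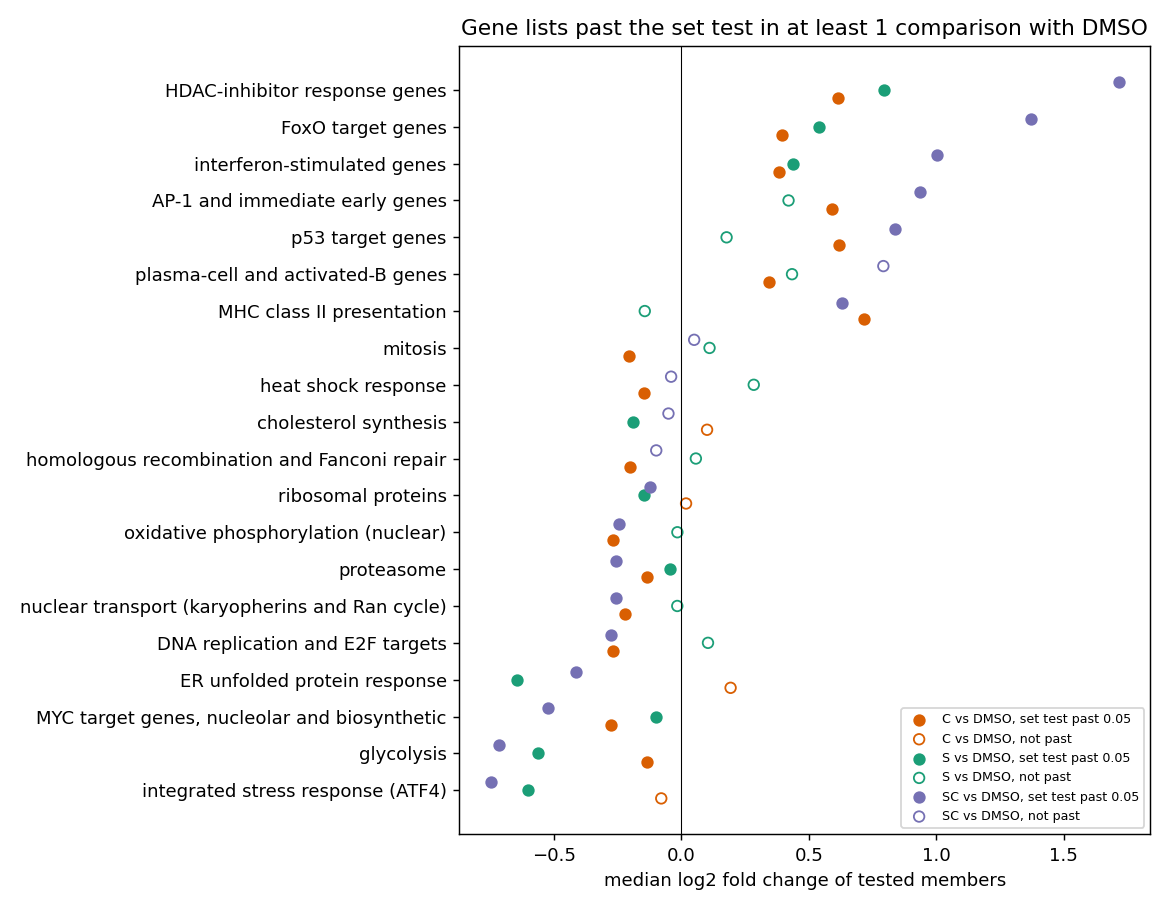
Median log2 fold change of the tested members (horizontal axis) of each gene list (vertical axis) that passed the set test in at least 1 comparison with DMSO, for C, S and SC; filled points passed at 0.05 and open points did not. The HDAC-inhibitor response list stood at 0.61, 0.79 and 1.72 in C, S and SC, and the ER list at 0.19, -0.64 and -0.41. Quantile normalization turned the ribosomal protein median in SC to 0.018.

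The direct comparison of S with C asks how the single agents differed. CDKN1A was lower in S (-2.84 ± 0.083, adjusted p = 1.35e-11), while XPO1 (0.87 ± 0.065, adjusted p = 8.02e-08), ARRDC3 (2.16 ± 0.12) and TP53 (1.21 ± 0.031, adjusted p = 4.33e-12) were higher. The list calls given below for this comparison all ended with an estimated correlation. In all, 5370 genes differed (limma), 2772 higher in S and 2598 lower, against 2543 higher and 2807 lower with trimmed-mean scaling. BCL2 (0.43 ± 0.042), PIK3CD (0.31 ± 0.047) and HDAC10 (0.37 ± 0.11) were higher in S. HDAC1 (-0.23 ± 0.033), AKT1 (-0.17 ± 0.051), MYC (-0.15 ± 0.034) and MCL1 (-0.15 ± 0.036) were lower. HDAC3 did not pass (0.090 ± 0.044, adjusted p = 0.0832) but did without S replicate 3, at 0.13, and after rescaling to equal sums, at 0.12.

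The genes that stood furthest above C in S were ARRDC3, WNT16 (1.85 ± 0.098) and the histones H2AC18 and H2AC19 (2.14 ± 0.072), H2BC17 (2.22 ± 0.53) and H2AC7 (1.92 ± 0.30), members of families with near-identical copies. Those furthest below were NCF1, which has near-identical pseudogenes (-3.16 ± 0.11), TMEM119 (-3.05 ± 0.10), SEL1L3 (-3.02 ± 0.057), TESC (-2.99 ± 0.11), LAT2, an adaptor of B-cell signalling (-2.87 ± 0.046), and GAMT (-2.85 ± 0.11).

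In S against C, 33 of 42 replication genes were higher and 2 lower, with MCM3 at 0.62 ± 0.028 (adjusted p = 1.19e-05, and adjusted p = 0.271 with an estimated correlation). For mitosis 24 of 36 were higher and 2 lower, with KIF20A at 0.97 ± 0.045 (adjusted p = 7.87e-04, and adjusted p = 0.271 with an estimated correlation). For oxidative phosphorylation the counts were 22 and 1 of 30, with SDHD at 0.83 ± 0.048 (adjusted p = 3.03e-04, and adjusted p = 0.271 with an estimated correlation), and for the heat shock response 13 and 2 of 18, with DNAJB1 at 0.77 ± 0.042 (adjusted p = 0.0220, and adjusted p = 0.271 with an estimated correlation). For nuclear transport they were 16 and 3 of 29, with NXF1 at 0.96 ± 0.044 (adjusted p = 0.0299, and adjusted p = 0.547 with an estimated correlation). For MYC targets they were 20 and 9 of 38, with ornithine decarboxylase ODC1 at 0.96 ± 0.029 (adjusted p = 0.0458, and adjusted p = 0.271 with an estimated correlation). Quantile normalization and a filter of 5 TPM ended the nuclear transport and MYC calls. Trimmed-mean scaling and a fit of the groups compared alone also ended the MYC call, as did leaving out DMSO replicate 1 or 3, C replicate 1, S replicate 2 or any SC library, with medians from 0.14 to 0.15.

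Of 17 MHC class II genes, 15 were lower in S than in C and 1 higher, with HLA-DQB1 at -1.80 ± 0.048 (adjusted p = 1.64e-05, and adjusted p = 0.0995 with an estimated correlation). In the ER list 16 of 16 were lower, with PDIA4 at -1.76 ± 0.037 (adjusted p = 2.28e-07, and adjusted p = 0.0526 with an estimated correlation). In the integrated stress response 18 of 23 were lower and 2 higher, with PSAT1 of serine synthesis at -2.20 ± 0.059 (adjusted p = 5.05e-05, and adjusted p = 0.271 with an estimated correlation). For glycolysis 16 of 22 were lower, with SLC16A3 at -2.34 ± 0.075 (adjusted p = 1.25e-04, and adjusted p = 0.366 with an estimated correlation). For cholesterol synthesis 13 of 19 were lower and 3 higher (adjusted p = 0.0220, and adjusted p = 0.271 with an estimated correlation). Of 23 B-cell identity genes 15 were lower and 6 higher, with CD22 at -1.38 ± 0.070 and CD79B at -0.78 ± 0.035 (adjusted p = 0.0254, and adjusted p = 0.271 with an estimated correlation). Ribosomal protein genes were lower for 33 and higher for 3 of 44 (adjusted p = 4.64e-04, and adjusted p = 0.441 with an estimated correlation), a call ended by quantile normalization. Adjusted over the list alone, the counts were the same except for nuclear transport (14 higher) and ribosomal proteins (34 lower).

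The comparison of SC with C asks what S added to C. XPO1 (0.67 ± 0.065, adjusted p = 1.52e-06), HDAC1 (0.38 ± 0.033) and TP53 (0.36 ± 0.031) were higher in SC, while CDKN1A (-0.42 ± 0.083) and MYC (-0.14 ± 0.034) were lower. ER stress genes were lower as a set. In all, 5011 genes changed (limma), 3284 higher and 1727 lower, against 2464 higher and 2598 lower after quantile normalization, 2435 higher and 2722 lower with trimmed-mean scaling and 1775 higher and 3410 lower with the empty stretch at 0. The all-gene median was 0.11, and -0.0049, -0.019 and -0.12 under these.

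The remaining targets did not pass. AKT1 (-0.086 ± 0.051) passed without SC replicate 3 (-0.14), with trimmed-mean scaling (-0.23) and with the empty stretch at 0 (-0.33). PIK3CD (-0.099 ± 0.047) passed without SC replicate 1 (-0.14) and under quantile normalization (-0.18), trimmed-mean scaling (-0.24) and the empty stretch at 0 (-0.34). BCL2 (0.081 ± 0.042) passed without C replicate 3, at 0.11, and after rescaling to equal sums, at 0.12, but turned to -0.16 with the empty stretch at 0. HDAC10 (0.25 ± 0.11) passed without C replicate 1, C replicate 3 or SC replicate 2, at 0.30, 0.30 and 0.36, and after rescaling to equal sums, at 0.29. HDAC3 (0.050 ± 0.044) and MCL1 (0.015 ± 0.036) were at -0.19 and -0.23 with the empty stretch at 0, and MCL1 at -0.13 with trimmed-mean scaling. MDK (1.99 ± 0.091), the apolipoprotein APOD (2.15 ± 0.19) and the histones H2AC18 and H2AC19 (2.39 ± 0.072), H2BC17 (2.25 ± 0.53) and H2AC7 (2.00 ± 0.30) rose furthest. HK2 (-1.89 ± 0.046), LCN15 (-1.53 ± 0.072), PIR (-1.49 ± 0.051), the cystine transporter SLC7A11 (-1.44 ± 0.16), the lactate transporter SLC16A3 (-1.43 ± 0.075) and PFKFB4 (-1.38 ± 0.12) fell furthest.

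Of 22 glycolysis genes in SC against C, 2 rose, 20 fell and 0 did not pass (adjusted p = 8.04e-10, and adjusted p = 0.202 with an estimated correlation). Of 16 ER response genes 0 rose, 16 fell and 0 did not pass, with HSPA5 at -1.02 ± 0.029 (adjusted p = 1.06e-10). For the integrated stress response 2 rose, 20 fell and 1 did not pass, with SLC7A5 at -1.24 ± 0.029 (adjusted p = 2.97e-10, and adjusted p = 0.140 with an estimated correlation). For MYC targets 3 rose, 24 fell and 11 did not pass, with SRM at -0.73 ± 0.034 (adjusted p = 5.49e-07). Ribosomal proteins (1 rose, 30 fell and 13 did not pass, adjusted p = 6.43e-08, and adjusted p = 0.279 with an estimated correlation), the proteasome (2 rose, 14 fell and 14 did not pass, adjusted p = 0.00108) and replication genes (8 rose, 16 fell and 18 did not pass, adjusted p = 0.0267, and adjusted p = 0.480 with an estimated correlation) were lower as sets, calls that quantile normalization ended; a filter of 5 TPM also ended the replication call. Mitosis genes were higher: 28 rose, 2 fell and 6 did not pass, with KIF20A at 0.94 ± 0.045 (adjusted p = 0.00659, and adjusted p = 0.426 with an estimated correlation). So were FoxO targets (15 rose, 2 fell and 1 did not pass, adjusted p = 0.00159, and adjusted p = 0.224 with an estimated correlation) with FBXO32 at 1.44 ± 0.079, and interferon-stimulated genes (22 rose, 1 fell and 6 did not pass, adjusted p = 0.00168, and adjusted p = 0.202 with an estimated correlation) with SAMD9 at 1.48 ± 0.12. HDAC-inhibitor response genes (13 rose, 3 fell and 2 did not pass, adjusted p = 0.0267, and adjusted p = 0.140 with an estimated correlation) included TXNIP at 1.49 ± 0.044, and AP-1 genes (10 rose, 1 fell and 3 did not pass, adjusted p = 0.0267, and adjusted p = 0.140 with an estimated correlation) included DUSP1 at 0.94 ± 0.086. Adjusted over the list alone, the counts were the same except for HDAC-inhibitor genes (4 fell), the integrated stress response (21 fell) and ribosomal proteins (2 rose).

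The comparison of SC with S asks what C added to S. CDKN1A rose from 0.243 ± 0.0404 to 5.68 ± 0.511 TPM (2.42 ± 0.083, adjusted p = 9.00e-11), HDAC1 by 0.60 ± 0.033, while TP53 (-0.85 ± 0.031), PIK3CD (-0.41 ± 0.047) and BCL2 (-0.35 ± 0.042, adjusted p = 6.39e-06) fell. Replication and respiration genes were lower as sets. In all, 5430 genes changed (limma), 3181 higher and 2249 lower, against 2306 higher and 2940 lower after quantile normalization, 2678 higher and 2941 lower with trimmed-mean scaling and 2039 higher and 3738 lower with the empty stretch at 0. The all-gene median was 0.068, and -0.050, -0.031 and -0.16 under these.

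XPO1 was lower in SC than in S (-0.19 ± 0.065, adjusted p = 0.0165), a call that ended after quantile normalization and without S replicate 3 or SC replicate 2, at -0.16 and -0.17. MCL1 rose (0.17 ± 0.036), a call that trimmed-mean scaling ended. It was at -0.075 with the empty stretch at 0. AKT1 (0.083 ± 0.051) passed without SC replicate 1, at 0.14, and after quantile normalization, at 0.16, and turned to -0.16 with the empty stretch at 0. MYC (0.0060 ± 0.034) passed after quantile normalization, at 0.14, and turned to -0.24 with the empty stretch at 0. HDAC3 (-0.040 ± 0.044) and HDAC10 (-0.12 ± 0.11) did not pass but were lower with the empty stretch at 0 (-0.28 and -0.31), as was HDAC3 with trimmed-mean scaling (-0.14) and HDAC10 after quantile normalization (-0.72). TMEM119 (3.45 ± 0.10), GMPR (3.08 ± 0.15), CNN2 (3.05 ± 0.077), MYOF (3.02 ± 0.074), MOXD1 (3.02 ± 0.068) and HOMER3 (2.96 ± 0.14) rose furthest. IGLL1 (-1.72 ± 0.072), GPR146 (-1.62 ± 0.057), HPS4 (-1.23 ± 0.036), GPER1 (-1.20 ± 0.040), LRRC26 (-1.12 ± 0.15) and RSC1A1 (-1.25 ± 0.35) fell furthest, the last no longer past the threshold with a pseudocount of 0.1.

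Of 42 replication genes in SC against S, 0 rose, 36 fell and 6 did not pass, with MCM4 at -0.59 ± 0.029 (adjusted p = 5.64e-12). Of 38 MYC targets 1 rose, 33 fell and 4 did not pass, with DKC1 at -0.55 ± 0.026 (adjusted p = 5.05e-11). For oxidative phosphorylation 0 rose, 27 fell and 3 did not pass, with UQCRC2 at -0.36 ± 0.032 (adjusted p = 1.86e-07). For nuclear transport 2 rose, 22 fell and 5 did not pass, with KPNB1 at -0.44 ± 0.028 (adjusted p = 8.95e-05, and adjusted p = 0.267 with an estimated correlation). The proteasome (1 rose, 20 fell and 9 did not pass, adjusted p = 2.87e-04) was lower as a set, which quantile normalization ended. MHC class II genes (15 rose, 1 fell and 1 did not pass, adjusted p = 2.87e-04, and adjusted p = 0.0710 with an estimated correlation) included HLA-DQA1 at 0.94 ± 0.042. Interferon-stimulated genes (26 rose, 2 fell and 1 did not pass, adjusted p = 2.87e-04, and adjusted p = 0.122 with an estimated correlation) included OAS3 at 1.91 ± 0.056. HDAC-inhibitor response genes (14 rose, 2 fell and 2 did not pass, adjusted p = 0.00513, and adjusted p = 0.0550 with an estimated correlation) included H1-0 at 1.25 ± 0.040. FoxO targets (14 rose, 0 fell and 4 did not pass, adjusted p = 0.00513, and adjusted p = 0.267 with an estimated correlation) included GADD45A at 1.27 ± 0.086, p53 targets (17 rose, 2 fell and 3 did not pass, adjusted p = 0.00833, and adjusted p = 0.130 with an estimated correlation) included GDF15 at 1.87 ± 0.11, and AP-1 genes (12 rose, 0 fell and 2 did not pass, adjusted p = 0.0103, and adjusted p = 0.0710 with an estimated correlation) included IER5 at 1.46 ± 0.065. Adjusted over the list alone, the counts were the same.

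The overlap of the single-agent changes asks whether C and S moved the same genes. Of 7435 genes, 3382 changed in both, 1652 higher in both, 785 lower in both and 945 in opposite directions. Which direction was the more common rested on scaling: 953 were higher and 1103 lower in both after quantile normalization, and 1326 were higher and 1182 lower in both with trimmed-mean scaling. Independent changes would give 1229, 517 and 1605 in genes not chosen by their changes. A choice of genes by the SC to DMSO ratio can favour genes that both agents moved alike. The distance from these numbers therefore cannot be read as agreement between the agents, and the simulations below held no such choice. Both comparisons use the same DMSO libraries, whose noise alone makes changes look alike. Over all genes the changes had the same sign for 64.8%, and for 66.8% in 50 simulations of unchanged groups against shared DMSO libraries. Noise made up the whole change in those simulations, so these shares do not show how much of the observed agreement was noise. The covariance of the changes across genes was 0.0633, and 0.00382 in the simulations, so 0.0595 of it was more than shared DMSO noise gave. The correlation across genes, which are not independent replicates, was 0.301, and 0.499 in the simulations, where noise makes up the whole change.

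The interaction term asks whether SC differed from the sum of the single-agent log2 changes. For most genes no departure was called: 6383 did not pass, the slope of SC on the sum was 0.953 across genes, and the median size of the departure was 0.125. In all, 1052 genes departed (limma), 602 above the sum and 450 below. Of these, 441 went further than the sum in its own direction and 611 against it. Low genes weighed on the split. With a pseudocount of 0.1, 489 stood above and 433 below, and with a filter of 5 TPM 468 above and 436 below. Among 527 genes under 1 TPM in DMSO, 111 stood above and 4 below. Of 36 mitosis genes 12 stood above the sum, and of 42 replication genes 16 stood below it. Both set calls ended with an estimated correlation (adjusted p = 0.293 for each). The signs of the departures rest on how SC is scaled: with trimmed-mean scaling 445 higher and 769 lower, and with the empty stretch at 0 223 higher and 3398 lower, where the all-gene median moved from 0.016 to -0.21.

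Among targets, BCL2 stood below the sum (-0.31 ± 0.059, adjusted p = 0.00460). XPO1 (-0.30 ± 0.092, adjusted p = 0.0486), PIK3CD (0.22 ± 0.066, adjusted p = 0.0470) and MYC (-0.17 ± 0.047, adjusted p = 0.0359) also passed, but barely. The XPO1 call remained only without DMSO replicate 3 or C replicate 2 and ended without any of the other 10 libraries, with values from -0.36 to -0.23 over the 12 fits. The PIK3CD call remained only without DMSO replicate 3 or SC replicate 2 and ended without any of the other 10, with values from 0.18 to 0.26, and PIK3CD turned to -0.021 with the empty stretch at 0. The MYC call remained only without DMSO replicate 2, S replicate 2 or SC replicate 3 and ended without any of the other 9, with values from -0.19 to -0.13. The XPO1 call also ended with a pseudocount of 0.1, a filter of 5 TPM or rescaling, the PIK3CD call with a pseudocount of 0.1, quantile normalization or trimmed-mean scaling, and the MYC call after quantile normalization. Each of the 3 ended without trend and robust moderation. TP53 (-0.14 ± 0.044) passed without S replicate 3, at -0.16, and after quantile normalization, at -0.19, and AKT1 (0.19 ± 0.073) without SC replicate 1, at 0.25. HDAC1 (-0.080 ± 0.047), HDAC10 (0.29 ± 0.15), MCL1 (0.14 ± 0.051), CDKN1A (-0.15 ± 0.12) and HDAC3 (0.0045 ± 0.063) did not pass, and with the empty stretch at 0 HDAC3 turned to -0.23 and TP53 (-0.38), CDKN1A (-0.35) and HDAC1 (-0.32) passed.

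IGLL1 stood furthest above the sum (1.48 ± 0.10): it was at 13.5 ± 1.09 TPM in C, 50.6 ± 3.77 in S and 14.7 ± 1.06 in SC. RRAD (1.48 ± 0.18), FMO5 (1.33 ± 0.21), SCHIP1 (1.301 ± 0.19), IGFBP2, which binds insulin-like growth factors (1.27 ± 0.19), and TNNC2 (1.24 ± 0.27) followed; RRAD reached 3.29 ± 0.494 TPM in SC from 0.0833 ± 0.144 in DMSO, and the RRAD and TNNC2 calls ended with a pseudocount of 0.1. MDK (-1.40 ± 0.13), CNN2 (-1.15 ± 0.11), SLC2A4RG (-0.84 ± 0.10), PPDPF (-0.82 ± 0.095), SERPINF1 (-0.74 ± 0.079) and the integrin ITGB1 (-0.71 ± 0.072) stood furthest below. SERPINF1 was at 63.8 ± 2.69 TPM in C and 63.8 ± 2.68 in SC.

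Of 36 mitosis genes, 12 stood above the sum and 0 below, 16 adjusted over the list alone, with CCNB1 at 0.38 ± 0.057 (adjusted p = 4.16e-06, and adjusted p = 0.293 with an estimated correlation); with the empty stretch at 0 the median of 0.22 turned to -0.015 and the CCNB1 call ended, at 0.14. Of 42 replication genes, 16 stood below and 0 above, 17 adjusted over the list alone, with CDC6 at -0.41 ± 0.058 and E2F1 at -0.46 ± 0.065 (adjusted p = 6.64e-07, and adjusted p = 0.293 with an estimated correlation). For MYC targets 15 of 38 stood below, 19 adjusted over the list alone, with NOLC1 at -0.30 ± 0.047 (adjusted p = 6.64e-07, and adjusted p = 0.0715 with an estimated correlation). For NF-kB targets 4 of 19 stood above, 7 adjusted over the list alone, with LTB at 0.98 ± 0.13 and NFKB2 at 0.43 ± 0.072 (adjusted p = 0.0101, and adjusted p = 0.293 with an estimated correlation), and the median of 0.19 turned to -0.051 with the empty stretch at 0. The NFKB2 call ended after quantile normalization, at 0.27. For cholesterol synthesis 7 of 19 stood above, 8 adjusted over the list alone, with FDFT1 at 0.30 ± 0.067 (adjusted p = 0.0127, and adjusted p = 0.293 with an estimated correlation), and the median of 0.12 turned to -0.12 and lost its call in that scaling, as did FDFT1, at 0.061.

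**Figure D4:**
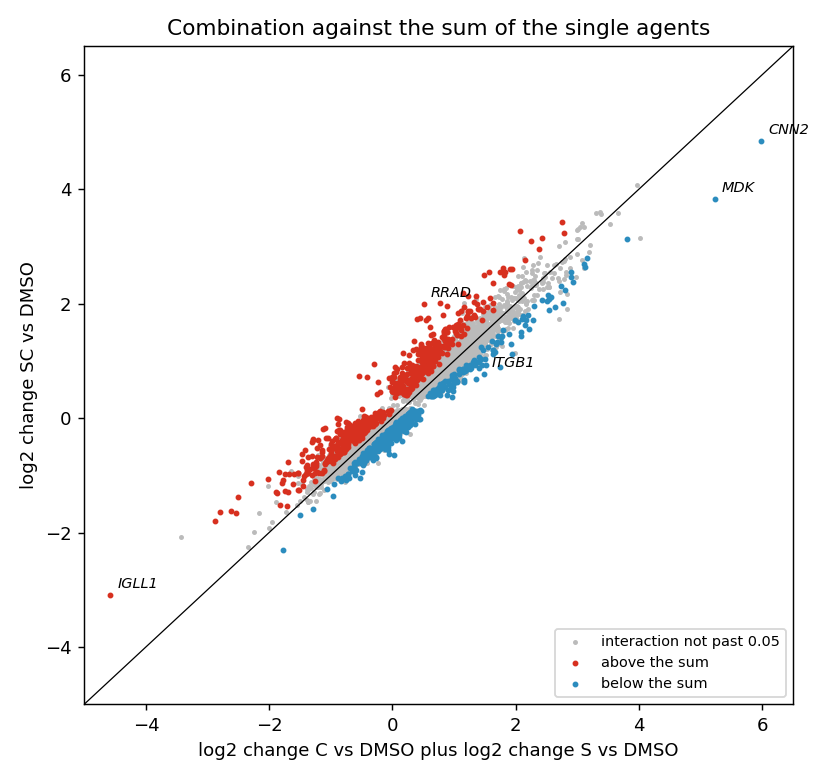
Log2 change of SC against DMSO (vertical axis) by the sum of the log2 changes of C and S (horizontal axis), with 1 point per gene (7435 genes); the line marks equality, red and blue points passed the interaction test above (602) and below (450) it. IGLL1 lay at -3.09 on the vertical axis and CNN2 at 4.84; with trimmed-mean scaling of the libraries, 445 higher and 769 lower passed.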

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

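The tests of technical explanations below were chosen after the results were seen; the splits of the libraries were planned before.

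The interaction count and 16 genes stand here because a test found that the effect of 1 agent differed with and without the other. In all, 1052 genes passed. Above the sum of the single-agent changes were IGLL1 (1.48), RRAD (1.48), FMO5 (1.33), SCHIP1 (1.301), IGFBP2 (1.27), TNNC2 (1.24) and PIK3CD (0.22). Below it were MDK (-1.40), CNN2 (-1.15), SLC2A4RG (-0.84), PPDPF (-0.82), SERPINF1 (-0.74), ITGB1 (-0.71), BCL2 (-0.31), XPO1 (-0.30) and MYC (-0.17). Some of these calls were fragile. Those of RRAD and TNNC2 ended with a pseudocount of 0.1. Of 12 fits without 1 library, 10 ended the XPO1 call, 10 the PIK3CD call and 9 the MYC call. Of 100 regroupings of the 12 libraries, the real one included, 2 gave as many genes; the highest other gave 2450 and kept the 3 DMSO libraries together as 1 group, and the other 98 gave 0. That decides nothing, since regrouping puts the single-agent effects into the residuals, whose median SD rose 3.42 times. With the main effects of C and S removed from each gene (ratio 1.05), 1 of the 100, the real grouping, gave as many, and the highest other gave 563. This argues against an arbitrary grouping of the libraries as the source of the count. It does not argue against an effect of how SC is scaled or of how the genes of the table were chosen.

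With 10 splits of 6 libraries a share is never under 0.1, and for each pairwise comparison 1 of the 10, the real split, gave as many genes. Fitted on the 6 libraries alone, the real counts were 4788 for C vs DMSO, 4894 for S vs DMSO, 6071 for SC vs DMSO, 4903 for SC vs C, 5510 for SC vs S and 5278 for S vs C. The highest other split gave 0 in each. That decides nothing, since every other split mixes the groups on each side and puts their difference into the residuals.

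XPO1 and ARRDC3 were higher in the libraries coded S, and CDKN1A and H1-0 in those coded C, while XPO1 inhibitors are known to raise XPO1 mRNA and HDAC inhibitors to raise CDKN1A and H1-0. Scaling between libraries would move all genes alike, but the S vs C changes of XPO1 and CDKN1A lay 3.71 apart, and an exchange of single libraries is argued against by 0 libraries correlating best with another group. Whether the treatment field is exchanged between the codes or each agent raised these genes in its own way cannot be told apart: of 21 marker genes past the threshold, 9 (42.9%) lay on the side that an exchange predicts. These were 2 of 5 XPO1-inhibitor markers and 7 of 16 HDAC-inhibitor response genes. An exchange of labels stays a candidate explanation, and an effect of the agents as labelled stays open too.

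Of 527 tested genes under 1 TPM in DMSO, 461 were higher in C and 2 lower. The expression filter keeps such genes almost only where other groups reach 1 TPM, and a gene near 0 has little room to fall, so this direction was largely fixed in advance. Without the filter, 774 of 1147 were higher and 18 lower, a count that the floor and the choice of genes in the table shape too. Markers of other cell types were among the genes that rose in C: 4 of 4 tested fibroblast markers (SPARC from 3.06 to 12.6 TPM, LUM from 0.0400 to 2.53), 4 of 4 T-cell and 3 of 4 epithelial markers. Neuronal genes went both ways: of 3 tested, 2 rose (MAP2 from 14.7 to 29.5 TPM, INA from 1.05 to 1.81) and TUBB3 fell from 189.5 to 79.3. RNA from fibroblasts would bring fibrillar collagens at high levels. The highest in C, COL1A1 (not tested), went from 0.0167 only to 0.273 TPM beside 2.75 TPM of FN1, and COL1A2 reached 0.0333 and COL3A1 0 TPM, which argues against fibroblast RNA as the whole cause. Selection of the table by the SC to DMSO ratio stays open as well. The order of the table followed the C to DMSO ratio more closely (rank correlation 0.867) than the S to DMSO ratio (0.694), so selection would favour genes raised in C, and the median S vs C change of -0.51 decides nothing. An effect of the agent coded C on these genes stays open too.

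In SC, 12 of 36 mitosis genes stood above the sum of the single-agent changes and 16 of 42 replication genes below it; the others did not pass, and both set calls ended with an estimated correlation (adjusted p = 0.293 for each). A factor on the SC libraries would move both lists alike, but the medians were 0.22 for mitosis and -0.12 for replication. The difference computed for this test was 0.337, which is not the distance between these 2 medians. By mistake it set the mitosis median against a single gene of the replication list. The side of 0 depends on that factor: with the empty stretch at 0 the medians were -0.015 for mitosis and -0.35 for replication. Selection by the SC to DMSO ratio treats genes of like SC vs DMSO change alike. Against the 100 other genes nearest in that change, mitosis genes lay 0.21 higher (95% interval over libraries 0.16 to 0.27). This argues against selection as the whole cause for them. Replication genes could be among those other genes and would raise the value, by an amount that was not computed. With the empty stretch at 0 the value was 0.21 too, which adds nothing, since a common factor on SC cancels in this comparison. For replication the comparison took, by mistake, that same single gene in place of the list, with a value of -0.10 (-0.27 to 0.062). The list itself was not compared in this way. Selection and an effect of the agents therefore cannot be told apart for replication genes. An effect of the combination on the cell cycle stays open, as untested, because cell-cycle phase was not measured here.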

How the results depend on the processing

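The scaling that puts the empty stretch of the SC ratio at 0 was chosen after seeing the data; the other alternatives were planned. Of 391 values of named genes, 169 kept their direction and side of the threshold under every alternative run and 13 reversed under at least 1. The minimum log2 change of 1 by itself ended 194 of these gene calls, by construction. For the 238 list tests the counts were 137 kept and 0 reversed, where the direction of a list is that of the set test, relative to the other genes. An estimated correlation by itself ended 63 of the list calls. The medians themselves changed sign for 4 of the lists called: ribosomal proteins in SC vs DMSO under quantile normalization (0.018), and with the empty stretch at 0 the interaction medians of NF-kB targets (-0.051), mitosis (-0.015) and cholesterol synthesis (-0.12). Leaving out each library in turn gave 4675 to 5002 genes for C vs DMSO, 4556 to 5055 for S vs DMSO, 5832 to 6149 for SC vs DMSO, 4551 to 5054 for SC vs C, 5023 to 5509 for SC vs S, 5029 to 5417 for S vs C, 725 to 937 for the interaction, 2084 to 2493 genes changed alike by both agents and 81 to 87 list calls. A minimum log2 change of 1, which by construction drops smaller changes, left 442 (C vs DMSO), 228 (S vs DMSO), 1244 (SC vs DMSO), 203 (SC vs C), 667 (SC vs S), 532 (S vs C) and 20 (interaction) genes, and 46 changed alike by both agents. List calls went from 82 to 19 with an estimated correlation, a test that also takes its p-values from 8 residual degrees of freedom in place of the number of genes; the parts of these 2 changes were not separated. With the replicate number as a block the interaction gave 1680 genes (934 above, 746 below); the numbers are not shown to pair all libraries, since 12 of 18 same-number correlations passed 0.1 and those of number 1 lay between -0.00052 and 0.0755. Those of numbers 2 and 3 lay between 0.121 and 0.425, and 10 of 12 libraries correlated best with their own number. These correlations use deviations from the group mean, which sum to 0 within a group. Where numbers 2 and 3 deviate in opposite directions, number 1 can lie near 0 even in paired libraries. Its low values thus do not argue against pairing, and a shared source stays open. The replicate block also brought past the test XPO1 in C vs DMSO (0.10), HDAC10 in SC vs C (0.25) and TP53 in the interaction (-0.14). With the empty stretch at 0 the interaction gave 3621 genes.

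With trimmed-mean scaling, SC vs DMSO turned to -0.15 for BCL2, -0.19 for HDAC3, -0.15 for MCL1 and -0.16 for MYC, and SC vs C to -0.13 for MCL1. With the empty stretch at 0, SC vs DMSO turned to -0.19 for BCL2, -0.23 for HDAC3, -0.20 for MCL1 and -0.21 for MYC. SC vs C turned to -0.16 for BCL2, -0.19 for HDAC3 and -0.23 for MCL1. SC vs S turned to -0.16 for AKT1, -0.075 for MCL1 and -0.24 for MYC. The interaction turned to -0.0078 for DHCR24, -0.23 for HDAC3 and -0.021 for PIK3CD. Dividing the SC libraries by a common factor lowers these values by construction; which scaling is right, and the cause of the reversals, was not tested. Depth is unknown, so its limit on low genes could not be computed.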

Other observations

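The genes and lists in this part were chosen after their values were seen. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, rose: 9 of 10 in S and 10 of 10 in SC, with the same counts adjusted over the list alone, and 3 of 10 in C (2 adjusted over the list alone). H2AC17 changed by 1.26 ± 0.21 in S and 1.76 ± 0.21 in SC, and H4C8 by 1.33 ± 0.24 and 1.74 ± 0.24. The set test did not pass in S (adjusted p = 0.108) or in SC (adjusted p = 0.0763). It passed in both with trimmed-mean scaling (medians 1.21 and 1.58) and without DMSO replicate 1 (medians 1.25 and 1.81). In SC it also passed after quantile normalization, with only the groups compared (1.75) and with the empty stretch of the SC ratio at 0 (1.52). These genes belong to families with near-identical copies, and the labels give oligo(dT) selection of mRNA.

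Of 12 germinal-centre genes, 9 rose and 2 fell in C, 8 rose and 1 fell in S, and 9 rose and 3 fell in SC. The counts adjusted over the list alone were the same. AICDA, the deaminase of antibody diversification, rose by 2.03 ± 0.071 in C, 0.87 ± 0.071 in S and 2.46 ± 0.071 in SC. The set test did not pass in C (adjusted p = 0.0584), where it passed without DMSO replicate 2 (median 0.57) or S replicate 2 (median 0.63), nor in S (adjusted p = 0.0717) or SC (adjusted p = 0.0968). In C it also passed with a filter of 5 TPM (0.48), quantile normalization (0.26), trimmed-mean scaling (0.58) and only the groups compared (0.63). It passed in S (0.28) and SC (0.83) with trimmed-mean scaling, and in SC with the empty stretch at 0 (0.78). Among pro-apoptotic BCL2 relatives, BMF changed by 1.61 ± 0.044 in C, 1.32 ± 0.044 in S and 2.38 ± 0.044 in SC, PMAIP1 by 1.31 ± 0.072, 0.14 ± 0.072 (adjusted p = 0.0993) and 1.64 ± 0.072, and BAX by 0.79 ± 0.061, -0.21 ± 0.061 and 0.48 ± 0.061. That list had 4 of 8 genes higher and 1 lower in C, 4 higher and 2 lower in S, and 6 higher and 2 lower in SC, and its set test did not pass (adjusted p = 0.234 in C, adjusted p = 0.804 in S and adjusted p = 0.636 in SC). Of the inhibitors of apoptosis in the table, 1 of 4 rose and 2 fell in SC: BIRC3 changed by -0.74 ± 0.17 and BIRC2 by 0.65 ± 0.10. In the PI3K-AKT-mTOR list of 24 genes, 11 rose and 9 fell in SC (adjusted p = 0.748), with 9 and 7 in C and 9 and 9 in S (10 and 9 in S adjusted over the list alone). Reference genes moved both ways in SC, 8 of 22 higher (7 adjusted over the list alone) and 8 lower (adjusted p = 0.507), with GAPDH at -0.54 ± 0.035 and ACTB at 0.37 ± 0.029.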
